A study of Mus musculus with 2 samples.

How the data were processed

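H3K9me2, dimethylation of lysine 9 of histone H3 and a mark of silent chromatin, was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in MC1-ZE7 mouse embryonic stem (ES) cells of the 129S6/SvEvTac strain. Per the labels, the cells were sorted by the fluorescence of Emerald, and the series describes the populations as Zscan4 positive and negative. Zscan4 is a family of zinc finger genes that only a small share of ES cells expresses at any moment. Each population has 1 library, Emerald-negative and Emerald-positive (the high fraction), so the comparison has no replicates.

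Per the labels' protocols, chromatin was fixed in 1% formaldehyde for 10 min, sonicated to fragments of 150 to 450 bp and precipitated with 3 µg of antibody. Libraries were selected for fragments of 200 to 300 bp on a gel. A second experiment amplified the DNA first and selected 200 to 500 bp. The labels do not say to which experiment the libraries belong or whether experiments were pooled.

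The deposited table gives, per the file headers, a signal for each library in 50 bins of 200 bp around each of 23946 regions, with bin centres from -4900 to 4900 bp. The signal was scaled by the authors: within a library all values were whole multiples of 1 step, cut to 2 decimals. A step of 1.12 in the Emerald-positive and 0.902 in the Emerald-negative library accounted for 100% of the values above 0 within a tolerance of 0.02. Dividing by the step recovered whole reads per bin. If both libraries were scaled to the same total, the Emerald-negative library was thus 1.24 times as deep as the Emerald-positive library. The ratios between libraries below rest on the scaling by the authors. The submitters' processing notes name the build mm9. The aligner, the treatment of duplicate reads, the total to which libraries were scaled and the origin of the regions are not given in the sources used here. Because each library was scaled by 1 constant and no input or spike-in was used here, a change of the mark by the same factor at every position would not appear in these values.

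The table pairs no region with a gene, and the gene table at hand describes GRCm38, so regions are given by their mm9 positions as deposited. Of 18 lists fixed before the data were examined, only the X-linked list could be placed, by chromosome; the other lists (genes of the 2-cell stage, pluripotency, germline and other cell types among them) were not analysed here. The rule for named genes was therefore applied to positions, as written: the 10 highest and the 10 lowest ratios among regions above the median signal.

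The main value per region was the mean deposited signal over all bins. The ratio between libraries was log2((Emerald-positive + 0.036)/(Emerald-negative + 0.036)), where the pseudocount was the 5th percentile of the nonzero region means. It understates the ratio of regions with few reads. Regions needed a read in both libraries, which left 23222. With 1 library per group no test between groups was made and no p-value is given. Ratios of recovered reads carry exact (Clopper-Pearson) 95% binomial intervals conditional on the total of both libraries, and the interval of the ratio of centre-to-flank ratios is a normal approximation on the log scale. These intervals cover counting error only, not differences between cultures, sorts or precipitations, and reads without molecular identifiers are not independent molecules. Intervals on ratios of median reads between sets of regions are not counting intervals. The one for chromosome 8 came from 1000 resamples of regions. They do not cover differences between preparations either. The spread that counting alone gives was obtained from 100 simulations in which the reads of each region were divided between the libraries by 1 common ratio. The X-linked list was set against 10000 random lists of the same size matched on mean signal in 20 bins. Of the regions, 6685 had a midpoint under 10 kb from the previous one, so their windows overlap and share reads; 18277 regions at least 10 kb apart served as an alternative.

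The counting intervals were tested on simulated data with the read totals of all 23946 regions and 200 regions changed. The interval excluded the common ratio for 42% of the regions changed 2-fold and 81% of those changed 4-fold. These shares depend on the read totals of the changed regions, and regions with fewer reads give lower shares. The interval held the true value for 96.5% of the unchanged simulated regions above the median total. Coverage in the real reads, whose squared deviations averaged 1.09 times the counting variance, was not tested. Alternatives to the pseudocount, window, filter, scaling and row summary were fixed before the data were examined. Leaving out regions over 100 reads, chromosome 8, its cluster of most-read regions, central peaks or overlapping windows was added after seeing the data. The analysis used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.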

Results

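H3K9me2 was profiled in 1 library of Emerald-negative and 1 library of Emerald-positive MC1-ZE7 ES cells, to compare the mark between Zscan4-negative and Zscan4-positive cells. The values covered 10 kb windows around 23946 regions (mm9) with a median width of 1111 bp (range 214 to 7077 bp). Summed over windows, there were 219416 reads of the Emerald-positive library and 270338 reads of the Emerald-negative library. A read in overlapping windows counts once in each. The median region had 7 reads (quartiles 4 and 12) in the Emerald-positive and 8 reads (quartiles 5 and 15) in the Emerald-negative library. In 724 regions at least 1 library had no read, which at this depth allows up to 3 reads in that library.

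The scaled H3K9me2 signal at these regions was nearly equal in the Emerald-positive and Emerald-negative libraries. Because of the scaling, this does not show whether the cells carried equal amounts of the mark. Over all windows the scaled signal averaged 10.3 per region in the Emerald-positive and 10.2 in the Emerald-negative library. The pooled ratio was 1.008-fold, with a counting interval of 1.003 to 1.014, which is too narrow because overlapping windows share reads. The median log2 ratio over 23222 regions was 0.0069, with quartiles of -0.39 and 0.42. The sign of so small a median depended on the scaling, and it was -0.0064 when each library was divided by its total. Levels of the libraries were correlated across regions, with Pearson's r of 0.744 for log2(reads + 1) and Spearman's rho of 0.766. These are correlations across regions, which are not independent replicates.

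H3K9me2 was at least 2-fold higher in Emerald-positive cells at 1253 regions (5.40%) and at least 2-fold lower at 1269 regions (5.46%). These counts followed the pseudocount: they were 377 and 390 at the 25th percentile of region signal and 1759 and 1883 at the 1st. Counting error alone gave a mean of 1090 regions higher (range 1032 to 1161) and 1185 lower (range 1095 to 1257) in 100 simulations. Regions were drawn independently in all simulations, while overlapping windows share reads, so the simulated ranges may be too narrow. The SD of the log2 ratio was 0.617 against 0.596 in the simulations. The mean squared deviation from the common ratio was 1.09 times the counting variance. The 95% counting interval lay above the common ratio at 442 regions and below it at 373. In 20 simulations such intervals averaged 313 above, with at most 379, and 280 below, with at most 309. The 99.9% counting interval lay above the common ratio at 9 regions and below it at 9. At that level the simulations averaged 4 regions above, with at most 9, and 3 below, with at most 7. With 1 library per population, the part of the spread beyond counting error could not be divided between populations and preparations.

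**Figure D1:**
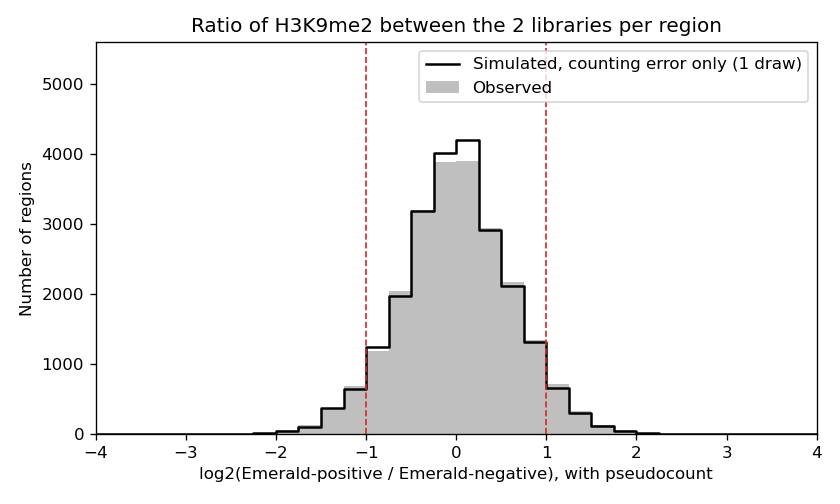
Distribution over regions of the log2 ratio of H3K9me2 signal, Emerald-positive over Emerald-negative (x axis), as number of regions (y axis). Grey bars are the observed regions, the black line is 1 simulation with counting error only, and red dashed lines mark a 2-fold difference; the observed quartiles were -0.39 and 0.42.

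The regions with the highest and lowest ratios among those above the median signal carried few reads, and their counting intervals were wide. The highest lay on chromosome 1 (84856931 to 84857887), with 27 reads in Emerald-positive and 4 in Emerald-negative cells, a ratio of 8.39-fold (interval 2.92 to 33.0). A region on chromosome 3 (80840509 to 80841469) followed with 14 reads against 2, or 8.70-fold (2.00 to 78.8). Another on chromosome 18 (73862464 to 73864458) had 15 reads against 3, or 6.21-fold (1.76 to 33.5). The 10 highest included 4 regions on chromosome 2, of which the one with the most reads (20855264 to 20857038) had 25 against 7, or 4.44-fold (1.87 to 12.2). The other 6 lay on chromosomes 2, 8, 9 and 12 with ratios of 4.72-fold to 5.80-fold. Ranks were taken with the pseudocount, and the ratios are of scaled reads without it.

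Among the 10 lowest, a region on chromosome 19 (54018752 to 54018989) had 3 reads in Emerald-positive and 25 in Emerald-negative cells, a ratio of 0.149 (interval 0.0288 to 0.489). A region on chromosome 5 (128112454 to 128113389) and a region on chromosome 7 (28931844 to 28933458) each had 2 reads against 18, a ratio of 0.138 (0.0155 to 0.577). A region on chromosome 14 (85090268 to 85091326) had 4 reads against 25, a ratio of 0.199 (0.0503 to 0.576). The other 6 lay on chromosomes 3, 4, 5, 11, 15 and 16 with ratios of 0.155 to 0.186. On the log2 scale with the pseudocount, the highest and lowest regions stood at 2.57 and -2.24. The most extreme regions in simulations with counting error alone averaged 2.42 and -2.44.

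H3K9me2 reads were depleted at the middle of the regions in both libraries. As no input was used, a lower level of the mark and a lower recovery of reads there cannot be told apart. In the central 10 bins, within 1000 bp of the reference point, the signal per 200 bp bin averaged 0.152 in Emerald-positive and 0.145 in Emerald-negative cells. In the flanks it averaged 0.219 and 0.218. The centre-to-flank ratio was 0.694 (counting interval 0.686 to 0.703) in Emerald-positive and 0.666 (0.658 to 0.673) in Emerald-negative cells. The depletion was deepest in the widest regions, although it did not follow width throughout. From the narrowest quartile of regions (up to 629 bp) to the widest (over 1667 bp), the ratios in Emerald-positive cells were 0.721, 0.736, 0.681 and 0.633. In Emerald-negative cells they were 0.684, 0.696, 0.664 and 0.613.

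The central depletion was slightly shallower in the Emerald-positive library. The log2 ratio of the centre-to-flank ratios was 0.061 (counting interval 0.038 to 0.084), and it was above 0 on 19 of 20 chromosomes, with a range of -0.0074 to 0.13. Chromosomes of the same 2 libraries are not replicates, so this count does not separate populations from preparations. Between 400 and 1000 bp from the reference point the log2 ratio between the libraries was 0.078 (0.052 to 0.10). Within 400 bp it was 0.039 (0.0030 to 0.075). From 1000 to 5000 bp the intervals of all 4 zones of 1000 bp held 0. From the quartile of regions with the fewest reads to that with the most, the difference in central depletion was 0.059 (-0.028 to 0.15), -0.077 (-0.14 to -0.011), 0.086 (0.038 to 0.13) and 0.082 (0.052 to 0.11). Over all regions it was 0.033 with a mean that left out the highest and lowest 1% of regions in each bin.

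**Figure D2:**
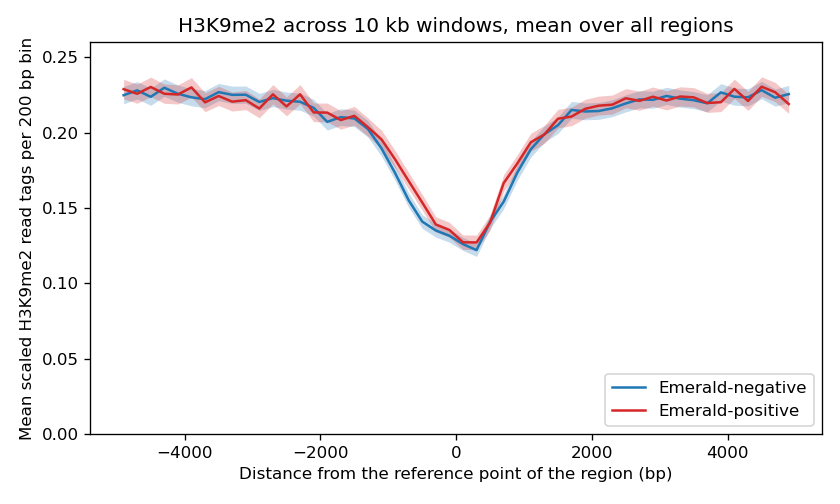
Mean scaled H3K9me2 read tags per 200 bp bin (y axis, from 0) against the distance from the reference point in bp (x axis) over 23946 regions. Lines are the Emerald-negative (blue) and Emerald-positive (red) libraries and shading is the 95% counting interval; both fall from about 0.22 in the flanks to about 0.13 at the centre.

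By chromosome, scaled H3K9me2 reads per region differed far more between chromosomes than between the libraries. Chromosome 8 had the highest median, 11.2 in Emerald-positive and 10.8 in Emerald-negative cells. The other autosomes had medians of 5.61 (chromosome 11) to 10.1 (chromosome 13) in Emerald-positive cells and of 5.41 to 9.93 on the same chromosomes in Emerald-negative cells. The X chromosome had 4.48 and 4.51, which in reads was 0.571 and 0.556 of the autosomal median. As no input was used, fewer copies of the X and a lower level of the mark cannot be told apart. The 4 regions on chromosome Y held 14 reads in the Emerald-positive and 22 in the Emerald-negative library. The log2 ratio between the populations, pooled per chromosome, ranged over the autosomes from -0.032 (interval -0.056 to -0.0080) on chromosome 8 to 0.056 (0.010 to 0.10) on chromosome 18. The value of chromosome 8 rested on a cluster of 10 heavily read regions, described last. Without them it was -0.0014 (-0.029 to 0.026), and chromosome 6 was then the lowest at -0.015 (-0.052 to 0.021).

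For the X-linked list, H3K9me2 was not detectably different between the populations at this depth. The pooled log2 ratio over 603 regions was -0.011 (interval -0.077 to 0.055). The median log2 ratio of the 544 X-linked regions with reads in both libraries was -0.038, against 0.0069 for all regions. It stood at the percentile 17.2 of 10000 random lists matched on signal. Of these regions, 260 lay above and 284 below the median of all regions, and 32 were at least 2-fold higher and 32 at least 2-fold lower in Emerald-positive cells.

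**Figure D3:**
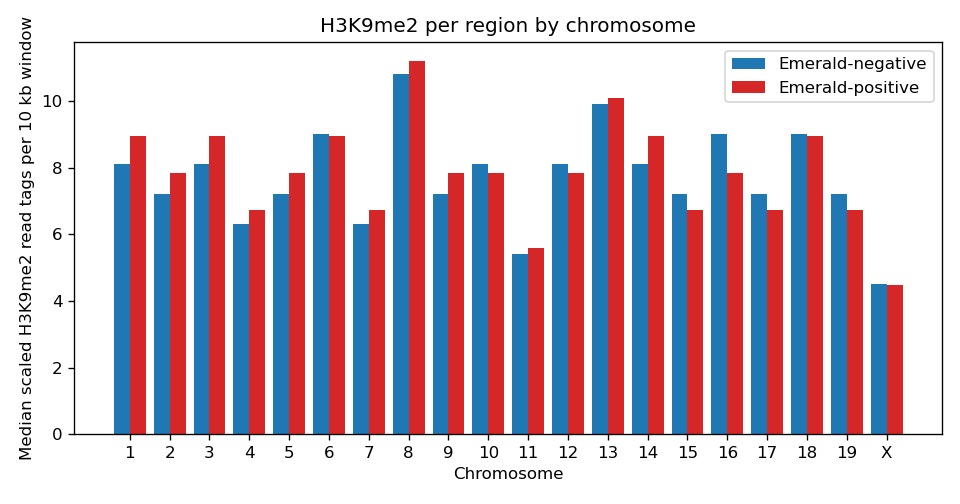
Median scaled H3K9me2 read tags per 10 kb window (y axis, from 0) for each chromosome (x axis) in the Emerald-negative (blue) and Emerald-positive (red) library; medians move in steps of 1 read, worth 0.902 and 1.12. Chromosome 8 stands highest, at 10.8 and 11.2, and the X chromosome lowest of those drawn, at 4.51 and 4.48; chromosome Y, with 4 regions, is not drawn.

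Of the 10 regions with the most reads, 9 lay in a cluster on chromosome 8, named here after its values were seen. The cluster's 10 regions between 19784470 and 20020749 held 959 to 1712 reads each, and their median was 74.4 times the median of all regions. Scaled reads were lower in the Emerald-positive library at 9 of the 10, with a pooled log2 ratio of -0.15 (interval -0.20 to -0.095). Over the 6 of them at least 10 kb apart the pooled ratio was -0.13 (-0.20 to -0.061). Single regions ranged from -0.39 (-0.58 to -0.20) to 0.016 (-0.16 to 0.19). The intervals of several held 0, and windows that overlap share reads. With no input and the treatment of duplicate reads unknown, copy number, read mapping and the mark cannot be told apart here. A smaller cluster of 8 regions on chromosome 11 (3023741 to 3192650), with 5 to 1011 reads each, had a log2 ratio of -0.085 (-0.19 to 0.017). Of these 8 regions, 4 were lower in the Emerald-positive library. The 132 regions over 100 reads held 7.68% of all reads, and their squared deviation from the common ratio was 2.00 times the counting variance, against 1.09 for the rest.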

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

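The median log2 ratio, 0.0069 as reported, was 0.17 in the central 10 bins (9771 regions), -0.0051 in the outer bins, 0.040 above the lower quartile of signal, -0.0046 with no filter, -0.0064 after division by each library's total and 0.22 with the median over bins, where 137 regions were left. With few reads per region these medians fall on ratios of small whole numbers. The 0.17 of the central bins is the value that 1 read in each library gives there, so it shows no direction. Counts of regions at least 2-fold higher and lower, 1253 and 1269 as reported, were 377 and 390 with a pseudocount at the 25th percentile and 1759 and 1883 at the 1st. They were 1815 and 1733 in the outer bins and 1430 and 1632 with no filter. Above the lower quartile of signal 830 were higher and 851 lower. In the central bins 1020 were higher and 719 lower, a larger share of the regions entered and a less even split. At such low counts the scaling favours the higher side, so the uneven split shows no direction. With the median over bins there were 0 of either kind. The X-linked median was 0.17 in the central bins (135 regions), again the value of 1 read in each library. It was 0.040 above the lower quartile and 0.22 with the median over bins (6 regions). The centre-to-flank ratios of the Emerald-positive and Emerald-negative libraries were 0.705 and 0.676 above the lower quartile, 0.639 and 0.625 with a trimmed mean, and 0.665 and 0.642 without regions over 100 reads, an alternative added after seeing the data. The trimmed mean lowered the log2 difference in central depletion to 0.033; the cause was not tested. One named region, on chromosome 3 (88634903 to 88636212), turned from -2.004 to 0.17 in the central bins, where each library had 1 read. Only 5 of the 20 named regions had reads in both libraries there and another of these, on chromosome 8 (73143109 to 73143609), went from 1.86 to 0.22 with 2 reads in each library. With equal reads these 2 values reflect only the scaling and show no direction. The other 3 kept their direction. With the median over bins no named region had a value. Under the remaining alternatives no named region that had a value changed direction. The alternative for rows sharing a gene symbol was not run, since no region carries one. No paired analysis was possible because each population has 1 library, and for the same reason no library could be left out. Depth limits single regions: with a median of 7 and 8 reads, most 2-fold differences lie within counting error.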

Other observations

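The tests of the most-read regions and the density trend on chromosome 8, and of background and fragment size in the central depletion were chosen after the results were seen.

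The order of the regions in the table, whose meaning is not given in the sources used here, went with the level and shape of H3K9me2 in both libraries. In the first twentieth of the table (1197 regions) the median was 28 reads per region over both libraries, against 13 in the fifth to twelfth twentieths. The last twentieth had 20. The central depletion of the whole set was missing in the first twentieth, where the centre-to-flank ratio was 1.04 (1.01 to 1.08) in Emerald-positive and 0.996 (0.964 to 1.03) in Emerald-negative cells. In the remaining regions it was 0.665 and 0.638. The difference between the libraries was uneven along the table. The ratios were 0.760 and 0.634 in the twelfth twentieth and 0.614 and 0.623 in the fifteenth. The last 100 regions had 2.31 and 1.69, which rested on 6 central peaks, and without these the ratios were 0.818 and 0.749. X-linked regions made up 1.67% of the first and 0.998% of the last twentieth, against 3.11% of the fifth to twelfth.

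H3K9me2 levels of neighbouring regions went together. Across pairs of regions 10 to 50 kb apart, the correlation of log2 reads was 0.429 over 14052 pairs, and at 200 to 1000 kb it was 0.216. For the deviations from the common ratio these correlations were 0.015 and -0.0021. Since counting noise made up most of those deviations, their correlation could not have exceeded 0.084, and depth sets how little it can show. Pairs share regions and are not independent.

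At 20 regions, chosen after their values were seen, H3K9me2 reads were concentrated near the centre, with at least 20 reads in the central 800 bp at over 5 times the density beyond 2000 bp. At 2 of them reads were denser between 400 and 1000 bp than within 400 bp, so those are not narrow central peaks. The largest, on chromosome 17 (4626258 to 4626811), had 249 central reads in Emerald-positive and 201 in Emerald-negative cells. The pooled log2 ratio of the central reads of the 20 regions was 0.35 (0.21 to 0.49), and 0.25 (0.085 to 0.42) without the largest. The regions did not all agree: scaled central reads were higher in Emerald-positive cells at 14 and lower at 6. The intervals may be too narrow. In regions over 100 reads, the largest among them, squared deviations from the common ratio were 2.00 times the counting variance. With no input and the treatment of duplicate reads unknown, copy number, read mapping and the mark cannot be told apart here either. Of the 20, 6 were among the last 100 regions of the table.

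For the high level at the first regions of the table, chromosome 8 and heavily read regions were left out first. The median of the first twentieth was still 1.733 times that of the rest (interval 1.63 to 1.93), and the centre-to-flank ratios stayed at 1.02 and 0.965. Against other regions of matched width the ratio was 1.8 (1.67 to 2.00), which argues against narrower regions as the cause. No biological explanation was tested. A candidate explanation that stays open is that the regions were ordered by another measurement, so that the first ones lie in chromatin carrying H3K9me2 in both populations.

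Chromosome 8 had a median of 22 reads per region over both libraries, 1.47 times that of the other autosomes (1.33 to 1.53 over resampled regions), and the 10th to 90th percentiles were 1.33 to 1.60 times as high. The most-read regions do not account for it, since the ratio was 1.4 (1.33 to 1.53) without regions over 100 reads. Neither does the density of regions: the median lay 5.839 residual SDs above the value of 13.6 predicted from the other 18 autosomes. An extra copy in the cultured line would give 1.5 and may be the source. Of the 10 Mb segments, 84.62% (11 of 13) exceeded the median of the other autosomes. That lies between the bounds set beforehand and does not decide it. The lowest segment stood at 1 times that median, and 61.8% of segments elsewhere exceeded it. Without input DNA, an extra copy and a higher level of the mark cannot be told apart here.

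For the shallower central depletion in the Emerald-positive library, more background reads spread evenly over the windows are argued against. Such reads would raise the least-read quartile of regions over the most-read quartile by 0.328 on the log2 scale. The observed difference was 0.02815 (-0.0024 to 0.059). The least-read quartile had 0.038 (0.0095 to 0.066) and the most-read quartile 0.0097 (-0.0014 to 0.021). Background gathered at the region centres was not tested. A few heavily read regions are not the whole cause, since the log2 difference was 0.05013 (0.026 to 0.074) without regions over 100 reads, although it was 0.033 with a trimmed mean. A different fragment size or tag placement could move reads over the edges of the depletion, and the log2 ratio within 400 bp of the centre, 0.03912 (0.0030 to 0.075), does not decide it. A difference between the sorted populations stays open and untested, with 1 library each.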
